A study of Mus musculus with 15 samples.

How the data were processed

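RNA of bone marrow precursors, immature macrophages and mature macrophages (3 libraries each) and of mature macrophages kept for 48 h without or with IL4 (3 libraries each) was measured by Ion Torrent sequencing. The labels say that RNA was taken by column with DNase and that 1 µg of total RNA went into each library. Per the labels, the authors aligned reads with HISAT2 2.0.5 and used edgeR, with no version given, and they name the builds GRCm38.p6 and GRCm39.p6. The counting program and the strand setting are not given in the sources used here. The authors deposited raw read counts per gene, 1 table for the 9 differentiation libraries (34245 genes) and another for the 6 libraries with or without IL4 (25965 genes). They also deposited log2 RPM (reads scaled to a common total) for the same genes, whose sorted values match between libraries, so these were also matched to a common distribution. The authors' own lists give an adjusted p-value (FDR) for genes under 0.05, 0.01 and 0.001 in each comparison.

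Gene identifiers and positions were checked against GENCODE M21, which is on GRCm38. Of 34162 genes with an identifier in the differentiation table, 34045 were in it and 34041 lay at an overlapping place. Of 25909 identifiers of the IL4 table, 24990 were in it. The 83 differentiation genes without an identifier, among them Itgam, held 0.338% of reads. Coordinates printed are those of the deposited tables. Start and end were those of M21 for 31723 of the 34045 identifiers of the differentiation table and 14753 of the 24990 of the IL4 table. For the others, Csf1r among them, they differ.

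The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, by group, which left 13359 genes in the differentiation table and 8936 in the IL4 table. Libraries were scaled by TMM, and glmQLFit and glmQLFTest were run without robust estimation and without covariates, the 9 differentiation libraries in 1 fit and the 6 others in another. P-values were adjusted by Benjamini-Hochberg over the genes tested, and genes under 0.05 were called. The comparisons were immature macrophages with precursors, mature with immature macrophages, mature macrophages with precursors, and IL4 with unstimulated cells. Levels in the text are CPM with the library totals scaled by TMM. The 35 gene lists, written before the data were examined, cover adhesion, motility and matrix degradation, cell states and metabolism, other cell types of bone marrow and signs of RNA quality. Lists of at least 5 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, two-sided, with adjustment over the lists of a comparison.

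The genes named follow a rule fixed before the data were examined. For each comparison it takes the 5 highest and 5 lowest log2 fold changes among genes called, changed at least 2-fold, with at least 10 CPM in the higher group, no overlap between the libraries of the groups and no predicted gene name. From each list of focus or cell state it takes up to 3 called members with the lowest p and at least 5 CPM, and fewer are printed where a list is described briefly. It always takes Csf1r, Adgre1, Cd68, Mpo, Mki67, Itgam and Mmp9 in differentiation and Arg1, Retnla, Chil3, Mrc1, Cdh1 and Mmp12 with IL4. From each list of other cell types or quality it takes the member with the highest mean CPM. Some genes so taken, and 1 of the focus lists, are not reported here. A fold against a group at 0 reads is a lower bound computed with 3 reads over the group and the pooled reads of the other group, and for groups with 1 to 3 reads the ratio is given with its exact 95% interval.

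The titles number the mice 1 to 3 in each group, which pairs libraries by label. The deposited column names of the IL4 table carry other numbers, whose meaning is not given. There the pairing rests on the titles, with columns taken in their order. An alternative adds this number as a replicate block. Other alternatives fixed before the data were examined were RLE scaling, DESeq2 1.42.0, no filter on low counts, a filter at 1 CPM in at least 3 libraries, limma on the deposited log2 RPM, a fit with only the 6 libraries compared, leaving out each library in turn, and an adjusted p under 0.001. For lists they were an estimated correlation, the block, fry, RLE and leaving out each library. Fits without a library filtered the genes anew, so the list members tested could differ. They tested 13445 to 13857 genes in differentiation and 8970 to 9131 with IL4. Leaving out both libraries of mouse 1 in the IL4 comparison was added after the data were seen. In the check of pairing, the deviations from the group mean correlated between libraries of the same mouse number by 0.591, 0.175 and 0.413 in the IL4 table. Those of different numbers correlated by -0.487 to 0.247 there, the highest between unstimulated library 3 and IL4 library 2, above the value of mouse 2. Those of the same number lay between -0.129 and 0.165 in the differentiation table.

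The procedure was tested on simulated data with 200 changed genes and the depth and spread of each comparison. Of genes changed 4-fold edgeR called 92.4%, 86.4%, 83.3% and 95.5% in the comparisons in the order above. Of genes changed 2-fold it called 17.9%, 25.4%, 14.9% and 53.7%. The adjusted threshold eases as more genes change, and far more genes were called in the data than these 200. The simulated shares therefore need not hold for the data. In the simulations edgeR called at most 6 unchanged genes. Raised sets of genes had a camera p of at most 2.19e-82, and random sets of 0.113 to 0.888. The authors' lists at 0.05 held 7468, 1494, 7291 and 1863 genes, of which 6117, 1308, 6235 and 1647 were also called here. Shared sequence between genes was measured as the share of 31-base words of a gene's transcripts found in another gene, with 1 word in 8 kept, in Python 3.11.15 with numpy 2.4.6. Figures were drawn with matplotlib 3.10.9. The deposited read counts of the authors' shorter lists were not used here because the tables of all genes hold them.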

Results

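Bone marrow cells of male C57BL/6 mice aged 8 to 10 weeks were grown in colony-stimulating factor 1 (CSF-1, the growth factor of the macrophage lineage), and their RNA was sequenced by Ion Torrent. Non-adherent precursors were taken after 2 days at 0.6 ng/ml CSF-1 in 15% FCS (fetal calf serum), and immature macrophages after a further 4 days at 12 ng/ml in 10% FCS, which all later steps used. Mature macrophages were taken after 10 days in all, the last 7 at 120 ng/ml. Mature macrophages of a separate table were kept for a further 48 h at 120 ng/ml CSF-1 with or without 20 ng/ml IL4 (interleukin 4, a cytokine of type 2 immunity). Each of the 5 groups had 3 libraries, numbered by mouse 1 to 3, so there were 15 libraries. The 9 differentiation libraries held 7897769 to 22167294 reads assigned to genes. Their group means were 15598812 ± 5809140 for precursors, 10543400 ± 2950350 for immature and 12271500 ± 2754130 for mature macrophages (SD, n = 3). The 6 libraries of the IL4 table were shallower, at 2408531 to 4214266 reads, with means of 3500980 ± 960725 reads without and 3348630 ± 457698 with IL4.

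Levels are CPM, read counts scaled to a common library total, as mean ± SD with n = 3, and changes are log2 fold change ± SE of the edgeR fit. A gene is said to have risen or fallen when its adjusted p was under 0.05. For each gene so named, the 3 libraries of 1 group lay above the 3 of the other, which chance gives for 10% of genes. Gene lists written beforehand were tested as sets with camera, whose adjusted p is given with a preset correlation between genes and, for calls, with an estimated correlation. Counts adjusted over the list alone are given where they differ from those over all genes. Coordinates are those of GRCm38. Counting intervals and lower bounds cover counting error only, and a gene at 0 reads in a group is given a bound from 3 reads over the group. Bounds use the pooled reads of each group, so deeper libraries weigh more than in the mean CPM, and leaving out 1 library of the group at 0 reads lowers a bound to no less than 0.527 times. Some log2 fold changes given without 1 library are fitted to very few reads in the lower group.

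The comparison of immature macrophages with precursors asks which genes changed as the cells became adherent, and the series title names adhesion, motility and matrix degradation. The design changes CSF-1 concentration, time in culture and serum together here. All 23 neutrophil granule genes and all 14 progenitor genes tested fell, while 23 of 29 macrophage genes, 25 of 28 lysosome genes and 21 of 22 cholesterol synthesis genes rose. All 5 lists passed camera, and with an estimated correlation the first 2 did (adjusted p = 0.0464 for both) and the other 3 did not (adjusted p = 0.177, 0.177 and 0.260). Csf1r, the receptor of CSF-1 (ENSMUSG00000024621, chromosome 18, 61105572 to 61132149), rose from 899.9 ± 111 to 2868 ± 1237 CPM (log2 fold change 1.67 ± 0.32, adjusted p = 0.00151). Adgre1, which encodes the macrophage surface protein F4/80 (ENSMUSG00000004730, chromosome 17, 57358686 to 57483529), rose from 195 ± 41.7 to 1540.1 ± 389 CPM (log2 fold change 2.98 ± 0.35, adjusted p = 7.96e-05). In all, 6568 of 13359 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 3009 were higher and 3559 lower in immature macrophages, 1884 and 2738 of them by at least 2-fold. By limma on the deposited log2 RPM 3790 were higher and 3136 lower.

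The 23 neutrophil granule genes had a median log2 fold change of -6.21 (camera adjusted p = 3.69e-15, adjusted p = 0.0464 with an estimated correlation). Mpo, the peroxidase of azurophil granules (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413), fell from 747 ± 199.9 to 9.69 ± 1.95 CPM (log2 fold change -6.27 ± 0.30). Lcn2, which binds iron siderophores, fell from 886 ± 156 to 5.78 ± 2.43 CPM, and Cxcr2, a chemokine receptor of neutrophils, fell from 236 ± 42.7 to 0.257 ± 0.222 CPM. The log2 fold change of Cxcr2 was -9.92, or -10.65 without immature library 3. Retnlg had 0 reads in immature macrophages against 246 ± 79.6 CPM in precursors, at least 2372-fold lower. The median of the progenitor genes was -6.64, or -6.15 with genes at 0 reads set to their bound (camera adjusted p = 6.55e-09, adjusted p = 0.0464 with an estimated correlation). Among them were the transcription factor Myb at -7.95 ± 0.31 and the stem cell marker Cd34 at -7.76 ± 0.48. Of 21 monocyte genes, 2 rose, 14 fell and 5 did not pass, with a median of -2.86 (camera adjusted p = 4.56e-05, adjusted p = 0.0429 with an estimated correlation). Ly6c2, a surface marker of inflammatory monocytes, fell from 460.0 ± 36.7 to 7.88 ± 1.42 CPM. All 11 MHC class II genes fell, with a median of -2.98 (camera adjusted p = 8.88e-06, adjusted p = 0.113 with an estimated correlation).

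Several lists of markers of other marrow cells also fell. Of 13 B cell genes, 1 rose, 12 fell and 0 did not pass, with a median of -9.02, or -8.09 with genes at 0 reads set to their bound (camera adjusted p = 2.29e-09, adjusted p = 0.0388 with an estimated correlation). The B cell receptor component Cd79a had 0 reads in immature macrophages, at least 902-fold lower than 86.4 ± 20.7 CPM in precursors. The beta globin gene Hbb-bs and the ectonucleotidase gene Nt5e were also at 0 reads, at least 1015-fold and at least 586-fold lower than in precursors. Dendritic cell genes (12 of 15 lower; camera adjusted p = 9.69e-08, adjusted p = 0.0343 with an estimated correlation) and eosinophil genes (10 of 10; camera adjusted p = 4.09e-08, adjusted p = 0.0429 with an estimated correlation) fell as lists. So did mast cell and basophil genes (8 of 8; camera adjusted p = 4.09e-08, adjusted p = 0.0930 with an estimated correlation) and megakaryocyte genes (11 of 12; camera adjusted p = 8.72e-06, adjusted p = 0.177 with an estimated correlation). Erythroid genes fell too (7 of 9; camera adjusted p = 0.000211, adjusted p = 0.113 with an estimated correlation). T and NK cell genes (4 of 6 lower) did not pass as a list (camera adjusted p = 0.127), but had an adjusted p = 0.00984 without precursor library 3, 0.0286 without immature library 1, 0.0157 without immature library 2 and 0.0449 without immature library 3. Endothelial genes (4 of 7 lower, or 5 adjusted over the list alone, with a camera adjusted p = 0.0665) likewise had an adjusted p = 0.0316 without precursor library 2, 0.0275 without immature library 1, 0.0164 without immature library 2 and 0.0222 without immature library 3. Fits without a library filtered the genes anew, so the members of these lists that were tested could differ. All 4 stromal genes tested fell, too few for camera. Among the most abundant members of these lists, Blnk, Cd28 and Tfrc rose, at 2.08 ± 0.31, 4.88 ± 0.41 and 1.23 ± 0.22. Hdc, Prg2, Acta2 and Vwf fell, at -6.47 ± 0.27, -7.02 ± 0.43, -3.69 ± 0.38 and -2.12 ± 0.53, and Pf4 (0.20 ± 0.41) and Tcf4 (0.22 ± 0.21) did not pass. Prg2 was at -7.64 without immature library 1.

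Of 29 macrophage genes, 23 rose, 1 fell and 5 did not pass, with a median log2 fold change of 2.33 (camera adjusted p = 4.09e-08, adjusted p = 0.177 with an estimated correlation). Gas6, a ligand of the receptors that bind apoptotic cells, rose from 9.39 ± 5.71 to 1648 ± 358 CPM, and Mrc1, the mannose receptor, rose from 68.1 ± 3.54 to 1729 ± 246 CPM. Trem2, a lipid-sensing receptor, rose from 144 ± 15.6 to 847 ± 72.9 CPM, and Cd68, a lysosomal membrane protein, rose from 138 ± 39.5 to 694 ± 219 CPM. Itgam, the integrin subunit CD11b, was at 1003 ± 195 CPM in precursors and 739 ± 92.1 CPM in immature macrophages and did not pass (-0.44 ± 0.20, adjusted p = 0.0965). Other genes with the largest increases were Speg, a kinase of striated muscle (from 0.134 ± 0.168 to 91.6 ± 15.0 CPM), Emp2 at 315-fold (95% counting interval 86.6 to 2610.3) and Samd4 at 259-fold (95% counting interval 88.1 to 1261). Lrrc14b rose 497-fold (95% counting interval 137 to 4111), but 99.1% of its 31-base words occur in another gene. The size of these increases depended on single libraries. Speg had a log2 fold change of 9.03. Without precursor library 2 the fit gave 10.92, against so few precursor reads that it does not estimate the size of the change. Emp2 was 166-fold higher without precursor library 2 and at least 160-fold higher without precursor library 3. Samd4 was 137-fold higher without precursor library 2, at least 197-fold higher without precursor library 3 and 124-fold higher without immature library 1, and Lrrc14b 229-fold higher without immature library 1. Of 28 lysosome genes, 25 rose, 0 fell and 3 did not pass, with a median of 1.65 (camera adjusted p = 1.64e-09, adjusted p = 0.177 with an estimated correlation). The lysosomal lipase Lipa and the tetraspanin Cd63 rose by 2.05 ± 0.23 and 2.41 ± 0.27. Of 22 cholesterol synthesis genes, 21 rose, 0 fell and 1 did not pass, with a median of 1.74 (camera adjusted p = 4.91e-08, adjusted p = 0.260 with an estimated correlation). The synthesis enzyme Mvd (ENSMUSG00000006517, chromosome 8, 122433601 to 122443422) rose from 22.2 ± 2.14 to 116 ± 22.1 CPM. Of 22 lipid handling genes, 13 rose, 2 fell and 7 did not pass, with a median of 1.33 (camera adjusted p = 0.00145, adjusted p = 0.177 with an estimated correlation). Fabp5 changed by 3.48 ± 0.31 and Dgat2 by -6.82 ± 0.52 (-7.55 without immature library 1).

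The adhesion and chemotactic receptor lists contained genes that rose beside genes that fell. Of 19 integrin genes, 4 rose, 12 fell and 3 did not pass (4 rose and 13 fell adjusted over the list alone), with a median of -1.84 (camera adjusted p = 0.05004). The list passed with replicate block (0.0465), and had an adjusted p = 0.0491 without precursor library 2, 0.0124 without precursor library 3, 0.0322 without immature library 1, 0.0251 without immature library 2 and 0.0256 without immature library 3. Itgb1, the common beta subunit, rose from 235 ± 10.1 to 709.7 ± 129 CPM. The collagen-binding subunit Itga1 and the platelet subunit Itga2b changed by -4.90 ± 0.38 and -4.84 ± 0.39. Of 29 adhesion receptor genes, 11 rose, 14 fell and 4 did not pass (11 rose and 15 fell adjusted over the list alone) (camera adjusted p = 0.504). Cadm1 rose from 23.6 ± 4.91 to 376 ± 29.0 CPM, while Pecam1 fell from 50.3 ± 11.2 to 0.473 ± 0.166 CPM. Of 37 focal adhesion and podosome genes, 9 rose, 17 fell and 11 did not pass (9 rose and 18 fell adjusted over the list alone) (camera adjusted p = 0.118). The adaptor Lpxn rose by 1.83 ± 0.21, and Nedd9 and the kinase Fgr changed by -4.85 ± 0.33 and -4.96 ± 0.35. Of 27 chemotactic receptor genes, 14 rose, 9 fell and 4 did not pass. Their median was 1.04, their mean -1.06 and the test pointed up (camera adjusted p = 0.457). The formyl peptide receptor Fpr2 fell from 46.3 ± 4.32 to 0.232 ± 0.0257 CPM.

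Genes of the matrix enzyme lists moved both ways. Mmp9, gelatinase B (ENSMUSG00000017737, chromosome 2, 164940780 to 164955850), fell from 1067 ± 192 to 0.163 ± 0.0387 CPM (log2 fold change -12.58 ± 0.93, adjusted p = 4.74e-06), and Mmp25 had 0 reads in immature macrophages, at least 532-fold lower. Of 22 metalloproteinase and inhibitor genes, 8 rose, 8 fell and 6 did not pass (9 rose and 8 fell adjusted over the list alone). Their median was 0.38, their mean -1.11 and the test pointed up (camera adjusted p = 0.825). Of 18 cathepsin genes, 11 rose, 4 fell and 3 did not pass, with a median of 1.998 (camera adjusted p = 0.00614, adjusted p = 0.440 with an estimated correlation). The asparaginyl protease Lgmn rose from 218 ± 73.4 to 2240.2 ± 87.7 CPM, and the granule protease Ctsg fell from 165 ± 14.5 to 2.97 ± 0.748 CPM. Of 20 genes of plasminogen activation and other matrix enzymes, 9 rose, 8 fell and 3 did not pass. Their median was 0.30, their mean -0.55 and the test pointed up (camera adjusted p = 0.829). Neutrophil elastase, Elane, and proteinase 3, Prtn3, changed by -5.001 ± 0.31 and -6.21 ± 0.25. Of 24 matrix component genes, 8 rose, 8 fell and 8 did not pass (camera adjusted p = 0.844). Fibronectin, Fn1, fell from 474 ± 40.9 to 0.546 ± 0.549 CPM, and Col18a1 rose from 2.59 ± 0.874 to 75.8 ± 30.3 CPM. The log2 fold change of Fn1 was -9.92, or -9.28 without immature library 1 and -10.93 without immature library 3.

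Of 38 cell cycle genes, 0 rose, 7 fell and 31 did not pass (0 rose and 3 fell adjusted over the list alone), with a median of -0.85 (camera adjusted p = 0.00953, adjusted p = 0.741 with an estimated correlation). The proliferation marker Mki67 fell from 1115 ± 88.9 to 265 ± 139 CPM. Of 67 replication histone genes, 0 rose, 50 fell and 17 did not pass (0 rose and 58 fell adjusted over the list alone), with a median of -2.13 (camera adjusted p = 2.81e-07, adjusted p = 0.590 with an estimated correlation), and Hist1h1c changed by -1.90 ± 0.40. Immature library 1 was low in both lists. Its mean log2 CPM was 3.80 against 5.73 and 6.27 over the cell cycle genes and 3.60 against 6.00 and 6.26 over the histones. The cell cycle list had an adjusted p = 0.115 without immature library 1. Of 24 interferon response genes, 4 rose, 0 fell and 20 did not pass (2 rose and 0 fell adjusted over the list alone), with a median of 0.51 (camera adjusted p = 0.0262, adjusted p = 0.741 with an estimated correlation), and Ifit2 rose from 17.7 ± 10.8 to 148 ± 80.8 CPM. Precursor library 3 was low in this list (mean log2 CPM 3.54 against 5.58 and 5.86), whose adjusted p was 0.416 without precursor library 3 and 0.0617 without immature library 1.

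Of 19 inflammatory genes, 5 rose, 8 fell and 6 did not pass (6 rose and 8 fell adjusted over the list alone) (camera adjusted p = 0.681). The receptor Tlr4 and the chemokine Ccl4 rose by 1.57 ± 0.17 and 2.47 ± 0.31, and Tnf changed by -2.37 ± 0.26. Of 32 genes of the IL4 response, 5 rose, 16 fell and 11 did not pass, with a median of -1.32 (camera adjusted p = 0.0313, adjusted p = 0.121 with an estimated correlation). That list's adjusted p was 0.0530 with replicate block and 0.0534 without immature library 2, and the lipoxygenase Alox15 fell from 51.3 ± 9.33 to 0.521 ± 0.369 CPM. Of 13 fusion and osteoclast genes, 5 rose, 5 fell and 3 did not pass. Their median was -0.19, their mean -1.22 and the test pointed up (camera adjusted p = 0.885). Among lists kept as signs of RNA quality, 10 of 13 mitochondrial genes fell (11 adjusted over the list alone), with a median of -3.46 (camera adjusted p = 0.0300, adjusted p = 0.713 with an estimated correlation). This call was lost at 0.0574 without immature library 3, and mt-Co1 did not pass (-0.82 ± 0.48). Of 15 immediate early and stress genes, 2 rose, 8 fell and 5 did not pass (3 rose and 8 fell adjusted over the list alone) (camera adjusted p = 0.193), and Atf3 rose by 2.91 ± 0.32. Of 80 ribosomal protein genes, 10 rose, 1 fell and 69 did not pass (0 rose and 0 fell adjusted over the list alone) (camera adjusted p = 0.109, and 0.0102 without immature library 2 and 0.0475 without immature library 3). The deposited log2 RPM moved the median log2 fold change of all genes tested from -0.07 to 0.10, so small changes depend on that scale.

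**Figure D1:**
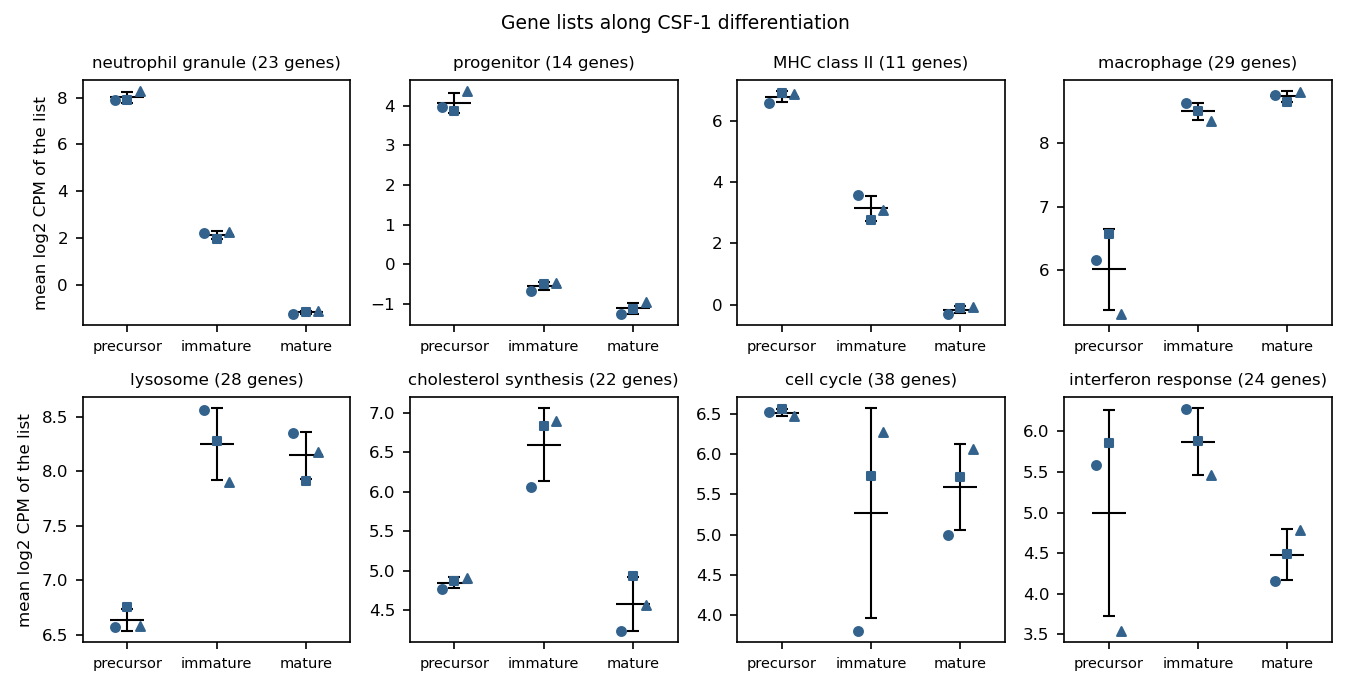
Mean log2 CPM of the tested members of 8 gene lists in precursors, immature and mature macrophages. Circles, squares and triangles are the libraries of mice 1, 2 and 3, the horizontal line is the mean and the bar the SD (n = 3). Neutrophil granule and MHC class II genes stepped down, progenitor genes were lower and macrophage and lysosome genes higher from the immature stage on, and cholesterol synthesis genes were highest in immature macrophages. The panels have separate vertical scales.

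The comparison of mature with immature macrophages asks what changed with a higher CSF-1 concentration and longer culture, 2 conditions that the design changes together. Of 22 cholesterol synthesis genes 21 fell, with a median log2 fold change of -1.996. Of 23 neutrophil granule genes 18 fell, with a median of -6.12, or -4.31 with genes at 0 reads set to their bound. Of 21 monocyte genes 9 fell and of 11 MHC class II genes 6 fell. Each of these 4 lists passed camera as lower, but with an estimated correlation none did (adjusted p = 0.272, 0.0809, 0.0703 and 0.247). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1991 of 13359 genes differed, 1005 higher and 986 lower in mature macrophages. Of these, 656 and 718 changed at least 2-fold. The counts depended on single libraries: 423 genes were higher and 584 lower without immature library 2, and 571 and 691 without immature library 1. When the precursors were left out of the fit, 633 were higher and 612 lower. Csf1r (-0.61 ± 0.31), Cd68 (-0.15 ± 0.38), Itgam (0.50 ± 0.20) and Mki67 (-0.12 ± 0.47) did not pass. Adgre1 did not pass either (0.70 ± 0.33, adjusted p = 0.182), but did without mature library 3 (0.98, adjusted p = 0.0391).

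Cholesterol synthesis enzymes and fatty acid desaturases were among the genes that fell. The cholesterol synthesis list had a camera adjusted p = 6.46e-16, adjusted p = 0.272 with an estimated correlation. Mvd fell from 116 ± 22.1 to 15.2 ± 3.76 CPM, and Hmgcs1, a synthase early in the pathway, fell from 238 ± 53.6 to 36.7 ± 14.7 CPM. Of 22 lipid handling genes, 1 rose, 9 fell and 12 did not pass (1 rose and 12 fell adjusted over the list alone), with a median of -1.07 (camera adjusted p = 0.00110, adjusted p = 0.334 with an estimated correlation). The desaturase Scd1 went from 95.1 ± 15.7 CPM to 0 reads, at least 1061-fold lower, and its paralog Scd2 fell from 534 ± 328 to 1.11 ± 0.994 CPM. Ch25h, a hydroxylase of cholesterol, rose from 0.722 ± 0.422 to 89.2 ± 22.6 CPM and was among the largest increases. The others were Id1, an inhibitor of transcription factors, at 614-fold (95% counting interval 169.6 to 5075), and the receptor Trem1 at 817-fold (95% counting interval 146 to 32298). Cd207, which encodes langerin, rose from 0.426 ± 0.738 to 80.0 ± 87.6 CPM, and Zfp618 rose from 0.206 ± 0.0490 to 26.7 ± 3.75 CPM. The size of several of these changes depended on single libraries. Cd207 had a log2 fold change of 7.81, or 7.07 and 7.21 without immature libraries 1 and 2 and 8.40 and 6.50 without mature libraries 1 and 2. All its immature reads were in immature library 3. Without that library the fit gave 13.07 against a group at 0 reads, which is not an estimate of the fold. Scd2 was at -8.89, or -9.90 without mature library 3, Id1 was 272-fold higher without mature library 2 and Trem1 at least 158-fold higher without immature library 1.

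Neutrophil granule genes fell further (1 rose, 18 fell and 4 did not pass (2 rose and 18 fell adjusted over the list alone); camera adjusted p = 6.46e-16, adjusted p = 0.0809 with an estimated correlation). Of 21 monocyte genes, 2 rose, 9 fell and 10 did not pass (4 rose and 10 fell adjusted over the list alone), with a median of -0.88 (camera adjusted p = 5.58e-05, adjusted p = 0.0703 with an estimated correlation). S100a9, a calcium-binding protein of neutrophils, Ngp, Camp and Mpo had 0 reads in mature macrophages, at least 806-fold, at least 361-fold, at least 151-fold and at least 108-fold lower. The monocyte chemokine receptor Ccr2 fell from 146 ± 32.8 to 1.34 ± 1.77 CPM, and F13a1, a subunit of coagulation factor XIII, fell from 219.5 ± 39.5 to 0.648 ± 0.567 CPM. Without mature library 3 their log2 fold changes went from -6.69 to -8.92 and from -8.48 to -7.82. The progenitor list did not pass (camera adjusted p = 0.0842, and 0.0415 without immature library 1). Of 11 MHC class II genes, 1 rose, 6 fell and 4 did not pass (1 rose and 7 fell adjusted over the list alone), with a median of -2.82 (camera adjusted p = 3.39e-05, adjusted p = 0.247 with an estimated correlation). Cd74, the invariant chain, fell from 175 ± 49.9 to 3.89 ± 1.92 CPM, and H2-Ab1 fell from 76.8 ± 23.4 to 0.608 ± 0.386 CPM. Ciita, the transactivator of class II genes, had 0 reads in mature macrophages, from 14.9 ± 10.3 CPM, at least 187-fold lower, or at least 102-fold without immature library 1. Of 15 dendritic cell genes, 0 rose, 8 fell and 7 did not pass, with a median of -3.88, or -1.39 with genes at 0 reads set to their bound (camera adjusted p = 8.08e-06, adjusted p = 0.0625 with an estimated correlation). Of 12 megakaryocyte genes, 0 rose, 4 fell and 8 did not pass (camera adjusted p = 0.000798, adjusted p = 0.432 with an estimated correlation).

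Of the most abundant members of the lists of other marrow cells, Cd28 changed by -4.23 ± 0.40, and Hdc and Prg2 went to 0 reads, at least 7.48-fold and at least 8.22-fold lower (at least 5.15-fold for Prg2 without immature library 1). Tfrc (-0.28 ± 0.22) and Pf4 (-0.75 ± 0.41) did not pass. Blnk (-0.59 ± 0.30) did not pass, with an adjusted p = 0.211, but did without mature library 3 (-0.99, adjusted p = 0.0266). The same held for Tcf4 at -0.50 ± 0.21 (0.138), which was at -0.72 (0.0419) without immature library 3, and Vwf at -0.70 ± 0.53 (0.414), which was at -1.73 (0.0191) without mature library 1. Acta2 passed at -1.52 ± 0.46 with an adjusted p = 0.0499. That value was 0.0968 with replicate block, 0.106 without immature library 1, 0.176 without immature library 2, 0.0705 without mature library 1 and 0.0921 without mature library 2. The T and NK cell list did not pass (camera adjusted p = 0.0547, 0.0453 with replicate block and 0.0316 without immature library 3).

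Genes of the adhesion lists again moved both ways. Of 19 integrin genes, 7 rose, 3 fell and 9 did not pass (10 rose and 3 fell adjusted over the list alone), with a median of 0.51 (camera adjusted p = 0.0886). Itga9 (ENSMUSG00000039115, chromosome 9, 118606690 to 118901003) rose from 7.28 ± 0.112 to 49.1 ± 6.00 CPM (log2 fold change 2.75 ± 0.21, adjusted p = 3.26e-05), and Itgb7 fell from 52.6 ± 22.9 to 4.26 ± 0.701 CPM. Of 37 focal adhesion and podosome genes, 7 rose, 4 fell and 26 did not pass (11 rose and 4 fell adjusted over the list alone) (camera adjusted p = 0.217). The podosome scaffold Sh3pxd2a and alpha-actinin, Actn1, rose by 1.46 ± 0.19 and 1.27 ± 0.18, and Tns1 changed by -3.54 ± 0.31. Of 29 adhesion receptor genes, 5 rose, 6 fell and 18 did not pass (9 rose and 7 fell adjusted over the list alone). Their median was 0.07, their mean -0.002 and the test pointed up (camera adjusted p = 0.948). Of 27 chemotactic receptor genes, 7 rose, 8 fell and 12 did not pass (7 rose and 10 fell adjusted over the list alone) (camera adjusted p = 0.153, and 0.0481 without immature library 3). Of 22 metalloproteinase and inhibitor genes, 4 rose, 5 fell and 13 did not pass (5 rose and 5 fell adjusted over the list alone) (camera adjusted p = 0.568). Of 18 cathepsin genes, 0 rose, 3 fell and 15 did not pass (camera adjusted p = 0.541). Of 20 genes of plasminogen activation and other matrix enzymes, 6 rose, 5 fell and 9 did not pass (7 rose and 8 fell adjusted over the list alone) (camera adjusted p = 0.568). Adam8, a membrane metalloproteinase, rose from 801 ± 200.4 to 4349.9 ± 423 CPM, and Plaur, the urokinase receptor, rose from 21.8 ± 3.54 to 120.0 ± 23.8 CPM. Mmp8 and Adam19 changed by -5.34 ± 0.63 and -6.27 ± 0.67. Mmp8 was at -6.90 without mature library 3, and Adam19 at -5.63 without mature library 1 and -8.37 without mature library 2. Mmp9 did not pass (3.27 ± 1.03, adjusted p = 0.0582, 0.0248 without mature library 2 and 0.0259 without mature library 3), and without mature library 1 it was at 1.27 (adjusted p = 0.256). Of 24 matrix component genes, 3 rose, 3 fell and 18 did not pass (camera adjusted p = 0.793). The matrix proteins Thbs1 and Vcan changed by -6.82 ± 0.59 and -3.78 ± 0.41, and Thbs1 was at -6.16 without immature library 1 and -7.53 without mature library 3. Of 29 macrophage genes, 5 rose, 2 fell and 22 did not pass (6 rose and 3 fell adjusted over the list alone) (camera adjusted p = 0.288). Among them the scavenger receptor Msr1 rose from 197 ± 90.7 to 1109 ± 151 CPM, and the complement gene C1qa rose from 656 ± 106 to 2572 ± 752 CPM. The receptor Axl fell from 43.3 ± 21.7 to 1.44 ± 1.45 CPM (log2 fold change -4.89, -4.28 without mature library 1 and -6.15 without mature library 3).

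Of 19 inflammatory genes, 6 rose, 1 fell and 12 did not pass (8 rose and 2 fell adjusted over the list alone), with a median of 1.03, or 0.99 with genes at 0 reads set to their bound (camera adjusted p = 0.00269, adjusted p = 0.432 with an estimated correlation). Tnf rose from 7.33 ± 2.01 to 73.2 ± 20.1 CPM, and Nlrp3 and Ccl4 rose by 0.99 ± 0.15 and 1.71 ± 0.30. Of 24 interferon response genes, 0 rose, 7 fell and 17 did not pass (0 rose and 10 fell adjusted over the list alone), with a median of -1.53 (camera adjusted p = 0.000128, adjusted p = 0.557 with an estimated correlation), and Mx1 fell from 39.4 ± 10.1 to 4.59 ± 1.81 CPM. Of 80 ribosomal protein genes, 0 rose, 11 fell and 69 did not pass (0 rose and 10 fell adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.000640, adjusted p = 0.557 with an estimated correlation). No gene passed edgeR's test among the 67 histones (Hist1h1c -0.58 ± 0.39) or the 13 mitochondrial genes (mt-Co1 0.18 ± 0.48), and Atf3 did not pass (0.33 ± 0.30). Cell cycle genes did not pass as a list (camera adjusted p = 0.274). The test pointed down at 0.0356 without immature library 1, in which these genes were low, and up at 0.000806 without immature library 3. The histone list had a camera adjusted p = 0.416, 1.08e-08 without immature library 1 and 0.0150 without mature library 3. Mature library 3 was high in mitochondrial genes (mean log2 CPM 5.97 against 2.21 and 1.41). The median of that list was 1.34, its mean 1.79 and its test pointed down (camera adjusted p = 0.948, and 0.000396 without mature library 3).

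**Figure D2:**
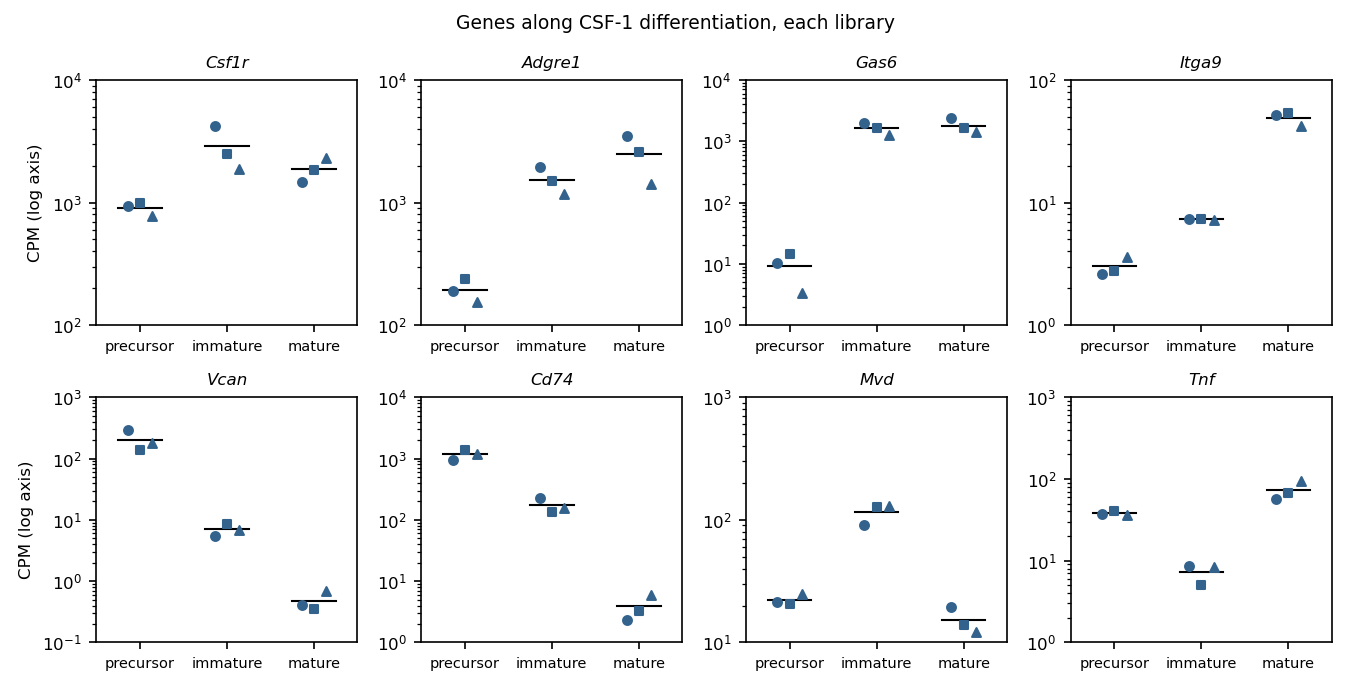
CPM on a log axis of 8 genes in the 9 differentiation libraries. Circles, squares and triangles are the libraries of mice 1, 2 and 3 and the line is the mean of each group (n = 3). Gas6 and Adgre1 were higher in every immature and mature library than in every precursor library, Itga9 and Tnf were higher in every mature than in every immature library, and Mvd was highest in immature macrophages. The panels have separate vertical scales.

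The comparison of mature macrophages with precursors spans the whole course, over which CSF-1 concentration, time in culture and serum changed together. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 7255 of 13359 genes differed, 3445 higher and 3810 lower in mature macrophages (2203 and 3022 at least 2-fold). By limma on the deposited log2 RPM 4067 were higher and 3457 lower. Abundant transcripts of neutrophils and monocytes in precursors went to 0 reads. S100a9 was at 6756 ± 1337 CPM in precursors, Ngp at 2353 ± 557, Mpo at 747 ± 199.9, Camp at 579 ± 83.8 and Ly6c2 at 460.0 ± 36.7 CPM. In mature macrophages they were at least 72890.2-fold, at least 25470.3-fold, at least 8208-fold, at least 6436-fold and at least 5161-fold lower. Ch25h, Nrcam, Shc2, Pla2g5 and the complement receptor Vsig4 had 0 reads in precursors. They reached 89.2 ± 22.6, 22.1 ± 10.5, 22.0 ± 9.65, 21.2 ± 3.91 and 18.8 ± 13.2 CPM, at least 1553-fold, at least 407-fold, at least 397-fold, at least 378-fold and at least 315-fold higher. Adgre1 rose from 195 ± 41.7 to 2495 ± 1029 CPM, the aspartic protease Ctsd rose from 1632 ± 289.7 to 24239.9 ± 3681 CPM, and C1qa rose from 49.6 ± 23.3 to 2572 ± 752 CPM. Cd68 rose by 2.19 ± 0.40. Csf1r rose from 899.9 ± 111 to 1877 ± 426 CPM (adjusted p = 0.0146, 0.0544 without precursor library 3 and 0.111 by limma on the deposited log2 RPM). Mki67 fell from 1115 ± 88.9 to 244 ± 143 CPM and Mmp9 fell from 1067 ± 192 to 1.61 ± 2.12 CPM (log2 fold change -9.31, or -11.30 without mature library 1). Itgam was at 1003 ± 195 and 1044 ± 93.1 CPM and did not pass (0.06 ± 0.20).

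Of 29 macrophage genes, 23 rose, 1 fell and 5 did not pass, with a median of 2.52 (camera adjusted p = 1.17e-07, adjusted p = 0.216 with an estimated correlation). Of 28 lysosome genes, 24 rose, 0 fell and 4 did not pass, with a median of 1.57 (camera adjusted p = 1.60e-07, adjusted p = 0.289 with an estimated correlation). Of 18 cathepsin genes, 12 rose, 5 fell and 1 did not pass. Their median was 1.99, their mean -0.20 and the test pointed up (camera adjusted p = 0.0227, adjusted p = 0.627 with an estimated correlation). The lists of integrins, adhesion receptors and focal adhesion and podosome genes did not pass (camera adjusted p = 0.740, 0.592 and 0.530). Nor did those of chemotactic receptors, metalloproteinases, plasminogen activation and matrix components (camera adjusted p = 0.658, 0.984, 0.521 and 0.984). Of 22 cholesterol synthesis genes, 2 rose, 5 fell and 15 did not pass (2 rose and 3 fell adjusted over the list alone) (camera adjusted p = 0.669). Neutrophil granule genes (1 rose, 22 fell and 0 did not pass; camera adjusted p = 1.10e-15, adjusted p = 0.0480 with an estimated correlation) and progenitor genes (1 rose, 13 fell and 0 did not pass; camera adjusted p = 1.17e-07, adjusted p = 0.0669 with an estimated correlation) fell as lists. Monocyte genes did so too (2 rose, 17 fell and 2 did not pass (3 rose and 17 fell adjusted over the list alone); camera adjusted p = 5.43e-06, adjusted p = 0.0341 with an estimated correlation). All 11 MHC class II genes fell, with a median of -8.23, or -7.91 with genes at 0 reads set to their bound (camera adjusted p = 1.60e-07, adjusted p = 0.0712 with an estimated correlation), and Cd74 fell from 1179 ± 204 to 3.89 ± 1.92 CPM. Of 67 histones, 0 rose, 65 fell and 2 did not pass (camera adjusted p = 1.17e-07, adjusted p = 0.724 with an estimated correlation), and Hist1h1c changed by -2.48 ± 0.41. Cell cycle genes did not pass as a list (camera adjusted p = 0.101, 0.0246 with replicate block). The IL4 response list fell (7 rose, 16 fell and 9 did not pass; camera adjusted p = 0.0321, adjusted p = 0.112 with an estimated correlation), with an adjusted p = 0.0526 without mature library 2. The interferon list did not pass (camera adjusted p = 0.669, and 0.00919 without precursor library 3, its low library).

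Among the lists of other cell types, B cell genes (12 of 13 lower; camera adjusted p = 8.03e-09, adjusted p = 0.0341 with an estimated correlation) and dendritic cell genes (14 of 15; camera adjusted p = 5.88e-09, adjusted p = 0.0182 with an estimated correlation) fell. Eosinophil genes (10 of 10; camera adjusted p = 1.89e-07, adjusted p = 0.0480 with an estimated correlation) and mast cell and basophil genes (8 of 8; camera adjusted p = 1.60e-07, adjusted p = 0.0936 with an estimated correlation) also fell. So did erythroid genes (8 of 9; camera adjusted p = 9.63e-05, adjusted p = 0.0936 with an estimated correlation), megakaryocyte genes (11 of 12; camera adjusted p = 1.23e-06, adjusted p = 0.164 with an estimated correlation) and T and NK cell genes (5 of 6; camera adjusted p = 0.0124, adjusted p = 0.2502 with an estimated correlation). Endothelial genes (5 of 7 lower) did not pass as a list (camera adjusted p = 0.0595), but had an adjusted p = 0.0277 without precursor library 2, 0.0194 without mature library 1, 0.0387 without mature library 2 and 0.0211 without mature library 3. Blnk and Tfrc rose by 1.49 ± 0.31 and 0.95 ± 0.22, and Acta2 and Vwf changed by -5.22 ± 0.43 and -2.82 ± 0.55 (Vwf -3.84 without mature library 1). Hdc and Prg2 had 0 reads in mature macrophages, at least 671-fold and at least 1028-fold lower, and Cd28 (0.65 ± 0.38), Pf4 (-0.55 ± 0.41) and Tcf4 (-0.28 ± 0.21) did not pass. Of 13 mitochondrial genes, 0 rose, 2 fell and 11 did not pass (0 rose and 0 fell adjusted over the list alone) (camera adjusted p = 0.0274, adjusted p = 0.833 with an estimated correlation). This list call was lost at 0.0775 without mature library 1 and 0.0944 without mature library 2. mt-Co1 (-0.64 ± 0.48) did not pass, and it was at -1.59 (adjusted p = 0.00163) without mature library 3, which was high in mitochondrial genes. Atf3 rose by 3.24 ± 0.32.

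Most genes called between precursors and immature macrophages were called in the same direction between precursors and mature macrophages. In both, 2333 genes were higher than in precursors, against 776 if calls were independent, and 2785 were lower, against 1015. Calls in opposite directions numbered 41 for genes higher and 30 for genes lower in immature macrophages. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.88. Both comparisons use the precursor libraries. In 20 simulations no group changed and both comparisons used the same simulated precursors, and the correlation averaged 0.475 with 0 shared calls. At most 2 genes were called in a simulated comparison. Shared calls were thus all but absent by design, and their number does not show what the common precursors add in the data. The covariance was 0.0833 in the simulations and 5.08 in the data.

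The comparison of mature macrophages with and without IL4 for 48 h asks which genes the cytokine changed. The IL4 response list rose (25 of 30 genes, median log2 fold change 4.18). MHC class II (5 of 6 genes higher), fusion and osteoclast (7 of 12) and lipid handling genes (9 of 19) passed camera as higher lists. With an estimated correlation none of these 3 did (adjusted p = 0.272, 0.162 and 0.168), and the lipid handling call was lost at 0.110 without unstimulated library 2. Interferon response (14 of 19 genes lower), inflammatory (9 of 13), cholesterol synthesis (14 of 19) and cell cycle genes (23 of 35) passed as lower lists. With an estimated correlation none of these 4 did (adjusted p = 0.272, 0.272, 0.284 and 0.354). Retnla, a secreted protein of alternatively activated macrophages (ENSMUSG00000061100, chromosome 16, 48842552 to 48844461), had 0 reads without IL4 and 8839.6 ± 8546 CPM with it, at least 34183-fold higher, or at least 14059-fold without IL4 library 1. Arg1, arginase 1 (ENSMUSG00000019987, chromosome 10, 24915208 to 24927470), rose from 5.11 ± 6.06 to 1804 ± 137 CPM (log2 fold change 8.38 ± 0.59, adjusted p = 6.11e-06), and its log2 fold change was 10.18 without unstimulated library 3. Mmp12, macrophage elastase (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), rose from 487 ± 383 to 19161 ± 3149 CPM (log2 fold change 5.30 ± 0.51, adjusted p = 4.05e-05, and 6.17 without unstimulated library 2). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 1855 of 8936 genes differed, 937 higher and 918 lower with IL4 (587 and 605 at least 2-fold). With replicate block, the mouse number as a term, 1447 were higher and 1436 lower.

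Of the 30 IL4 response genes, 25 rose, 3 fell and 2 did not pass (camera adjusted p = 2.62e-21, adjusted p = 0.00845 with an estimated correlation). Ocstamp and Dcstamp encode membrane proteins needed for macrophage fusion. Ocstamp went from 0 reads to 342 ± 37.6 CPM, at least 1219-fold higher, and Dcstamp rose from 0.513 ± 0.291 to 61.2 ± 7.74 CPM. Cdh1, E-cadherin, rose 181-fold (95% counting interval 61.6 to 881; 338-fold without unstimulated library 3), and the kinase Matk rose from 3.79 ± 0.860 to 114 ± 13.2 CPM. Mrc1, the mannose receptor, is in this list but fell from 1781 ± 457 to 982 ± 226 CPM (log2 fold change -0.86 ± 0.23, adjusted p = 0.0236). This call was lost at 0.0717 without unstimulated library 1, 0.0554 without unstimulated library 3, 0.0537 without IL4 library 1 and 0.106 without IL4 library 2, where the log2 fold change was -0.66, -0.86, -0.78 and -0.75. With replicate block it was -0.85 (adjusted p = 0.00104), and the level with IL4 was 0.391, 0.631 and 0.693 times that without for mouse numbers 1, 2 and 3. Both rest on the pairing of libraries by title, while the column names carry other numbers, whose meaning is not given. Chil3, a chitinase-like protein, was listed at 0 reads in all 6 libraries and gave no fold. Lrrc32, the coagulation factor F7 and the ribonuclease Rnase2a also had 0 reads without IL4. With it they were at 99.5 ± 24.7, 90.2 ± 8.51 and 59.4 ± 17.96 CPM, at least 361-fold, at least 325-fold and at least 218-fold higher. Of 12 fusion and osteoclast genes, 7 rose, 1 fell and 4 did not pass (7 rose and 2 fell adjusted over the list alone), with a median of 2.71 (camera adjusted p = 0.000294, adjusted p = 0.162 with an estimated correlation). The lists share members: 6 of these 12 genes and 11 of the 30 IL4 response genes also lie in another list. Of 6 MHC class II genes, 5 rose, 0 fell and 1 did not pass, with a median of 3.97 (camera adjusted p = 0.000302, adjusted p = 0.272 with an estimated correlation). Cd74 rose from 21.7 ± 14.4 to 336 ± 121 CPM and H2-Ab1 from 0.576 ± 0.622 to 13.4 ± 12.8 CPM. The log2 fold change of Cd74 was 4.01, or 4.64 without unstimulated library 2. That of H2-Ab1 was 4.70, or 4.01 without unstimulated library 1, 5.59 without unstimulated library 2 and 3.57 without IL4 library 2.

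Adhesion genes moved both ways with IL4. Of 14 integrin genes, 5 rose, 4 fell and 5 did not pass. Their median was -0.002, their mean 0.49 and the test pointed up (camera adjusted p = 0.361). Itgax, the integrin subunit CD11c, rose from 34.2 ± 28.7 to 3107 ± 999.7 CPM, Itgb3 rose from 3.81 ± 0.584 to 69.9 ± 14.5 CPM and Itga8 fell from 51.0 ± 13.4 to 2.58 ± 2.13 CPM. The log2 fold change of Itgax was 6.56, or 7.44 without unstimulated library 2, and that of Itga8 was -4.33, or -5.20 without IL4 library 3. Of 21 adhesion receptor genes, 8 rose, 5 fell and 8 did not pass (camera adjusted p = 0.273), and syndecan 1, Sdc1, and the tetraspanin Cd9 rose by 4.05 ± 0.43 and 1.76 ± 0.17. Of 33 focal adhesion and podosome genes, 9 rose, 6 fell and 18 did not pass (11 rose and 7 fell adjusted over the list alone). The median of this list was -0.03, its mean 0.16 and its test pointed up (camera adjusted p = 0.597). Cortactin, Cttn, and Actn1 rose by 2.95 ± 0.34 and 1.68 ± 0.20, and Tns1 changed by -2.56 ± 0.26. Of 18 chemotactic receptor genes, 7 rose, 4 fell and 7 did not pass (7 rose and 5 fell adjusted over the list alone) (camera adjusted p = 0.858). The chemokine receptor Ccr1 rose from 3.34 ± 2.47 to 73.9 ± 19.0 CPM (log2 fold change 4.61, or 5.24 without unstimulated library 2), and the nucleotide receptor P2ry12 and the sphingosine phosphate receptor S1pr1 changed by -4.22 ± 0.26 and -2.68 ± 0.16.

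Of 13 metalloproteinase and inhibitor genes, 4 rose, 0 fell and 9 did not pass (4 rose and 2 fell adjusted over the list alone). The list did not pass (camera adjusted p = 0.0696, and 0.0358 without unstimulated library 3, 0.0441 without IL4 library 1 and 0.0296 without IL4 library 2). The collagenase Mmp13 rose from 6.44 ± 3.14 to 708 ± 311 CPM, and Mmp19 rose from 50.8 ± 9.79 to 507 ± 58.1 CPM. Of 14 cathepsin genes, 7 rose, 1 fell and 6 did not pass (camera adjusted p = 0.0744). Ctss rose from 649.9 ± 43.0 to 2194 ± 110.2 CPM, Ctsl rose by 1.62 ± 0.19, and Ctsc changed by -2.26 ± 0.25. Of 15 genes of plasminogen activation and other matrix enzymes, 3 rose, 5 fell and 7 did not pass (3 rose and 6 fell adjusted over the list alone) (camera adjusted p = 0.273). Plaur rose from 209 ± 21.2 to 745 ± 45.7 CPM, and the transglutaminase Tgm2 rose from 89.0 ± 39.1 to 359 ± 147 CPM. Of 13 matrix component genes, 4 rose, 4 fell and 5 did not pass. Their median was -0.19, their mean 0.27 and the test pointed down (camera adjusted p = 0.597). Mfge8 rose from 102 ± 28.3 to 810.2 ± 114 CPM, fibronectin, Fn1, rose 327-fold (95% counting interval 90.3 to 2710.1; 203-fold without IL4 library 3), and nidogen 2, Nid2, fell from 36.1 ± 1.82 to 1.86 ± 0.216 CPM.

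Of 19 interferon response genes, 0 rose, 14 fell and 5 did not pass (0 rose and 15 fell adjusted over the list alone), with a median of -1.67 (camera adjusted p = 8.39e-11, adjusted p = 0.272 with an estimated correlation). Oas2 fell from 87.2 ± 18.6 to 3.75 ± 0.984 CPM, Ifit1 fell from 34.0 ± 20.2 to 1.81 ± 0.432 CPM, and the chemokine Cxcl10 fell from 37.1 ± 32.7 to 0.708 ± 0.0826 CPM. Without unstimulated library 1 the log2 fold changes of Ifit1 and Cxcl10 went from -4.21 to -3.59 and from -5.65 to -4.59. Of 13 inflammatory genes, 0 rose, 9 fell and 4 did not pass (0 rose and 10 fell adjusted over the list alone), with a median of -1.88 (camera adjusted p = 1.30e-05, adjusted p = 0.272 with an estimated correlation). The receptors Tlr2 and Nlrp3 changed by -3.23 ± 0.31 and -2.11 ± 0.32. The other largest decreases were in Ms4a6b, 129-fold (95% counting interval 44.0 to 630.2), Siglece, 42.2-fold (95% counting interval 14.2 to 207), Tmem176b at -5.18 ± 1.06 and the desaturase Fads2 at -5.05 ± 0.66. Without 1 library Tmem176b was at -3.72 (unstimulated library 1) and -8.76 (IL4 library 1), and Fads2 at -4.41 (IL4 library 1) and -6.88 (IL4 library 2). Siglece was 78.4-fold lower without IL4 library 1. Of 35 cell cycle genes, 0 rose, 23 fell and 12 did not pass (0 rose and 30 fell adjusted over the list alone), with a median of -1.07 (camera adjusted p = 8.39e-11, adjusted p = 0.354 with an estimated correlation), and Tk1 fell from 40.5 ± 7.25 to 11.7 ± 5.45 CPM. Of 16 histone genes, 0 rose, 4 fell and 12 did not pass (1 rose and 11 fell adjusted over the list alone) (camera adjusted p = 0.000577, adjusted p = 0.429 with an estimated correlation). Of 19 cholesterol synthesis genes, 0 rose, 14 fell and 5 did not pass (0 rose and 16 fell adjusted over the list alone), with a median of -1.27 (camera adjusted p = 1.12e-08, adjusted p = 0.284 with an estimated correlation), and Sc5d changed by -2.60 ± 0.41. Of 19 lipid handling genes, 9 rose, 1 fell and 9 did not pass (10 rose and 2 fell adjusted over the list alone), with a median of 0.47 (camera adjusted p = 0.00455, adjusted p = 0.168 with an estimated correlation). The nuclear receptor Pparg and the lipase Lpl rose by 2.51 ± 0.27 and 2.26 ± 0.23.

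Of 27 macrophage genes, 6 rose, 13 fell and 8 did not pass (6 rose and 16 fell adjusted over the list alone), with a median of -0.86 (camera adjusted p = 0.00432, adjusted p = 0.284 with an estimated correlation). The transcription factor Maf fell from 123 ± 8.43 to 12.4 ± 5.19 CPM, and the Fc receptor Fcgr1 fell from 101 ± 7.62 to 9.60 ± 3.68 CPM. The monocyte list did not pass (camera adjusted p = 0.0537, 0.0207 with replicate block, 0.0181 without unstimulated library 2 and 0.0268 without IL4 library 2). Of 28 lysosome genes, 7 rose, 1 fell and 20 did not pass. Their median was -0.07, their mean 0.39 and the test pointed up (camera adjusted p = 0.273), and the proton pump subunit Atp6v0d2 rose from 51.8 ± 30.4 to 1760.2 ± 269 CPM. The share of reads from lysozyme, Lyz2, was 4.35% without and 1.51% with IL4. Of 10 immediate early and stress genes, 5 rose, 0 fell and 5 did not pass (camera adjusted p = 0.00140, adjusted p = 0.168 with an estimated correlation), and Atf3 rose from 196 ± 35.7 to 1585 ± 115 CPM. No gene passed edgeR's test among 19 ribosomal protein genes (camera adjusted p = 0.273; Rps9 0.03 ± 0.18). Among abundant members of the lists of other cell types, Tfrc and the eosinophil chemokine receptor Ccr3 rose by 1.46 ± 0.23 and 3.32 ± 0.44, and Pf4 changed by -2.25 ± 0.25. Cd28 (-0.45 ± 0.53), Tcf4 (-0.40 ± 0.19) and Eng (0.16 ± 0.19) did not pass. Blnk (0.58 ± 0.21) passed with replicate block (adjusted p = 0.00692 against 0.0714) and by DESeq2 (0.0475). Hist1h2ak (-1.17 ± 0.49, adjusted p = 0.126) passed with replicate block (6.18e-05) and at 0.0404 without unstimulated library 1.

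Abundant genes were missing from the IL4 table. Of 3992 genes with at least 50 CPM in mature macrophages, 296 had 3 reads or fewer in the 6 libraries, so levels are not compared between the tables and such genes could not be tested. Across all comparisons, 21 of 213 genes named by the rule share at least 20% of their 31-base words with another gene, which limits how well their reads can be assigned. They include Chil3, Ctsd, Ctsl, Fpr2, Hbb-bs, Ly6c2, Lyz2, Mmp19, Cd9, mt-Co1, Hist1h2ak and Lrrc14b.

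**Figure D3:**
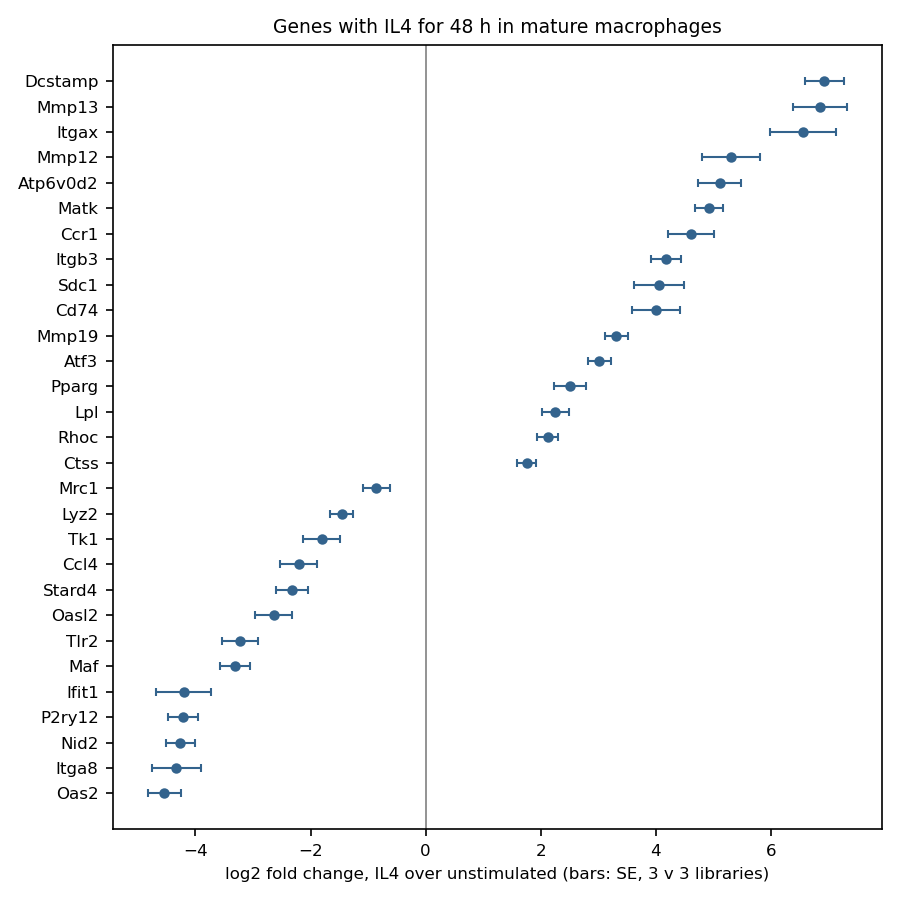
Log2 fold change of 29 genes in mature macrophages with IL4 over those without, from the edgeR fit. Points are estimates and bars are SE (3 libraries against 3), and the vertical line marks no change.

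Whether IL4 moved the genes that differentiation had moved was asked of the genes that differed at least 2-fold between precursors and mature macrophages. Of 1698 such genes higher in mature macrophages and tested in the IL4 table, 276 rose and 273 fell with IL4 (camera adjusted p = 0.836, median log2 fold change -0.02). Of 1144 genes lower in mature macrophages, 171 rose and 158 fell (camera adjusted p = 0.836). Their median was -0.03, their mean 0.09 and the test pointed down. These 4 overlaps were 1.60, 1.56, 1.47 and 1.34 times those of independent calls, and that difference was not tested. The 2 steps were tested in the same way, and none of their 4 sets passed. Of genes higher in immature macrophages than in precursors 226 rose and 277 fell with IL4 (camera adjusted p = 0.311), and of those lower 172 rose and 148 fell (0.962). The median of the latter was -0.04, their mean 0.14 and the test pointed up. Of genes higher in mature than in immature macrophages 119 rose and 94 fell (0.483), and of those lower 63 rose and 86 fell (0.105). For example, Gas6 rose over the course (7.57 ± 0.56) and fell with IL4 from 1094 ± 279 to 196 ± 42.5 CPM.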

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

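Leaving out both libraries of mouse 1 was the 1 alternative chosen after the result was seen, and all others were fixed before the data were examined. RLE scaling, DESeq2, the filters and, for differentiation, the replicate block left each count of called genes within 1.5 times the value reported, and the sign of each gene named in the text held under RLE, DESeq2 and the filters. At an adjusted p under 0.001 the higher and lower counts fell to 1026 and 1159 (immature against precursors), 87 and 123 (mature against immature), 1408 and 1558 (mature against precursors) and 313 and 207 (IL4), as a stricter threshold must. Mature against immature gave 633 and 612 with only the 6 libraries of the groups. Leaving out each library, it gave 423 to 1266 higher and 584 to 1436 lower. With replicate block IL4 gave 1447 and 1436 genes, including all 1855 called without it. Without mouse 1 it gave 855 and 803. Beyond the calls given in the report, the block changed no other call of a gene or list named. Of simulated 2-fold changes edgeR recovered 53.7% with IL4. It recovered 17.9% in immature against precursors, 25.4% in mature against immature and 14.9% in mature against precursors. These shares need not hold for the data.

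With an estimated correlation 0 lists were higher and 6 lower in immature macrophages against precursors, 0 and 0 in mature against immature, 0 and 5 in mature against precursors and 1 and 0 with IL4. The estimate replaces a preset of 0.01 by medians of 0.121 and 0.0549. By fry, which does not compare a list with other genes, 22 were lower against precursors in immature macrophages, 3 were higher and 16 lower in mature against immature, and 10 were higher with IL4. Leaving out each library gave 1 to 2 lists higher in mature against immature. Under fry the direction turned for chemotactic receptors (adjusted p = 0.00733), metalloproteinases (3.07e-05) and plasminogen activation (0.000623) in immature against precursors. It also turned for plasminogen activation in mature against precursors (3.46e-05) and chemotactic receptors with IL4 (0.0261). The cell cycle list in mature against immature turned without 1 library, over a range of 0.000806 to 0.754.

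Genes named that did not pass the test changed sign as follows, and the cause was not tested. Leaving out each library gave -0.27 to 0.60 for Pf4 and -0.033 to 0.44 for Tcf4 in immature against precursors. In mature against immature it gave -0.037 to 0.56 for Atf3, -0.77 to 0.54 for mt-Co1, -0.61 to 0.15 for Cd68 and -0.68 to 0.21 for Mki67, and mt-Co1 was -0.0069 with replicate block and -0.13 by limma. In mature against precursors Itgam was -0.35 by limma and ranged over -0.022 to 0.23. With IL4, Cd28 ranged over -1.04 to 0.47 and Rps9 over -0.051 to 0.19, and Rps9 was -0.23 by limma and -0.086 without mouse 1.

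Some calls of named genes depended on the method, and the cause was not tested. By limma on the deposited log2 RPM, the calls of Acta2 in mature against immature (adjusted p = 0.0911) and Csf1r in mature against precursors (0.111) were lost. It called Itgam in immature against precursors (0.0196), and Cd28 (0.0155) and mt-Co1 (0.0352) in mature against precursors. DESeq2 called Itgam in immature against precursors (0.0444) and Mmp9 in mature against immature (0.0256), as did edgeR with no filter for Mmp9 (0.0258). With only the 6 libraries of the groups, mt-Co1 was called in immature against precursors (0.0228) and Acta2 was not in mature against immature (0.147).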

Other observations

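The tests of carry-over by the B cell and erythroid lists were chosen after the result was seen. So were those of the scaling of Mrc1 and of the libraries of mouse 1. The same holds for the intervals on overlap and length of genes listed at 0. Lysozyme, Lyz2, took 0.762% of reads in precursors, 2.003% in immature and 4.04% in mature macrophages.

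Immature macrophages kept 1.51% ± 0.170 of the precursor level of neutrophil granule transcripts (SD, n = 3), 9.29% ± 1.40 of monocyte and 13.4% ± 4.14 of MHC class II transcripts, members that mature macrophages express left out. RNA or reads carried over from all precursors would keep a like share of every lineage. The erythroid list kept 0.0855% ± 0.120, at most 0.170 times the neutrophil share, which argues against such carry-over as the whole source. That share rests on 6 reads in the immature libraries, and counting error was not included when the bound was applied. The B cell list kept up to 0.406 times, between the bounds set. The progenitor (1.10% ± 0.230), T and NK cell (1.05% ± 0.987), dendritic (1.93% ± 0.374), eosinophil (0.790% ± 0.328) and mast cell lists (0.573% ± 0.173) lay nearer to the neutrophil share and the megakaryocyte list kept 3.77% ± 0.204, so carry-over from a part of the precursors stays open. A few early granulocytes among the cells may be a source: early granulocyte genes kept 1.39% ± 0.209 and late neutrophil genes 0.267% ± 0.206, 5.22 times less, in a test written before these values were seen. The late share rests on 15 reads in the immature libraries and the early one on 320. By gene, kept shares overlapped, from 0% to 4.32% among the early genes and from 0% to 0.728% among the late. Low expression by the macrophages themselves was not tested.

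Of genes with at least 50 CPM in mature macrophages, 296 had 3 reads or fewer in the IL4 table, 225 of them 0, among them Gapdh, Pgk1, Rpl3 and 49 of 80 ribosomal protein genes. Reads shared with another gene, by near-identical sequence or by overlapping exons, may be part of the cause for most. Of these genes 66.6% share at least 20% of their 31-base words with another gene, against 7.71% of the others (Fisher's exact p = 1.23e-122). Words in an exon that overlaps another gene also count as shared, so this does not tell those sources apart. Among genes under 20%, 47.5% overlap an exon of another gene (95% interval 37.3 to 57.8%) against 32.6%. Among those that also overlap no exon the median length was 0.832 times that of the others (0.705 to 0.959). Neither overlap in genes under 20% nor length was decided. The same genes had at least 50 CPM in the differentiation table, so shared sequence or overlap alone cannot account for their loss. A difference in how the 2 tables were processed would also be needed, and it was not tested. Start and end matched M21 for 14753 of 24990 identifiers in the IL4 table and 31723 of 34045 in the differentiation table. No biological explanation was tested, since both groups of the table are affected.

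Mrc1, which is in the IL4 response list, was lower with IL4, at -0.86 ± 0.23 (adjusted p = 0.0236). Loss of reads to near-identical sequence is argued against, with 0% of Mrc1 words in another gene, while the scaling between libraries stays open: the log2 fold change was -1.12 to -0.86 over 4 scalings, but these shifted the median gene by at most 0.0191, too little to test it. Paired by title, the libraries of mouse 1 gave the lowest ratio of IL4 to unstimulated CPM, 0.391, against 0.631 and 0.693 for mice 2 and 3. With replicate block, which removes what both libraries of a mouse number share, the log2 fold change was -0.85 (adjusted p = 0.00104). The pairing is uncertain, since the column names carry other numbers, whose meaning is not given. Unstimulated libraries 2 and 3 were at 1318 and 1792 CPM and IL4 libraries 2 and 3 at 832 and 1242 CPM, so another pairing would give other ratios. Without mouse 1 the log2 fold change was -0.58 ± 0.25 and the call ended (adjusted p = 0.139), with fewer libraries and a smaller change. The labels name no batch. A part that comes from another difference between the 2 libraries of mouse 1 cannot be told apart from the effect of IL4. An effect of IL4 on Mrc1 stays open as a hypothesis.

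The 6 libraries of a comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. In each comparison 1 of them, the real one, reached the real number of calls. The real splits called 6568, 1991, 7255 and 1855 genes and the highest of the other splits 0, 25, 0 and 0. The other splits place libraries of both groups on the same side, which widens the spread within sides. Their low counts therefore decide nothing.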
